A study of Mus musculus with 10 samples.

How the data were processed

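Gene expression was measured in mouse liver on Affymetrix MG_U74Bv2 oligonucleotide arrays. Per the labels, 10 arrays came from 5 groups: male mice carrying a transgene for the active nuclear form of human SREBP-1a (TgSREBP-1a) or of human SREBP-2 (TgSREBP-2) with wild type littermates, and male mice whose liver lacks SCAP (Scap-/-) with wild type controls. SREBPs are transcription factors of lipid synthesis, and SCAP escorts their precursors to the site of activation. The transgenic study used mice aged 12 to 16 weeks that ate a diet rich in protein and poor in carbohydrate for 2 weeks. The Scap study used chow-fed mice aged 10 to 12 weeks, which had 4 injections of polyinosinic-polycytidylic acid, an inducer of the Cre recombinase, with livers taken 14 days after the last one. In each group, RNA of 5 livers was combined into 1 pool (20 µg) and hybridised to 2 arrays.

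The deposited values are log2 expression values, which the submitters' processing notes ascribe to RMA with no version given. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of a probe set. The deposited arrays had medians between 5.625 and 5.662, as such a normalization leaves them. No genome build was named, so no coordinates are given.

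Of 12477 probe sets, 66 control probe sets were left out and 12411 were tested. Gene symbols came from the platform's annotation table: 10581 probe sets had 1 symbol (7542 genes, 2205 of them with more than 1 probe set), 178 had several and 1652 had none. A RefSeq table of assembly GRCm38.p6 was used to update symbols and changed 0 of them.

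A linear model with 1 coefficient per group was fitted to all 10 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that the 5 groups shared 1 estimate of the spread between duplicate hybridisations. Adjusted p-values are Benjamini-Hochberg values over the 12411 probe sets, two-sided. A probe set was called at an adjusted p under 0.05 and a change of at least 1.5-fold. The comparisons were TgSREBP-1a, TgSREBP-2 and Scap-/- against their wild type pools, the transgenic lines against each other, and the wild type pools against each other. Errors are limma standard errors on the log2 scale unless named otherwise, with n = 2 arrays per group. Since the arrays of a group share 1 pool, every p-value compares pools against hybridisation error and says nothing about the spread between mice. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.115.

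The combined pattern was the set of probe sets called higher in both transgenic lines and lower in Scap-/-. The list higher in both lines, which shares no arrays with the Scap study, was tested against the list lower in Scap-/- with Fisher's exact test. Correlations of fold changes were taken across probe sets, which are not independent replicates. For the transgenic lines, which share their wild type arrays, correlations and overlaps simulated without any change stand beside the observed ones. The simulated arrays hold hybridisation noise only, without differences between pools.

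Gene lists (27, with 782 entries) were fixed before the data were examined, for lipid and sterol pathways, other liver metabolism, stress and inflammation, and markers of cell types. Each gene was represented by its probe set with the highest mean. Counts of called members are given over all probe sets and adjusted over the list alone. The median log2 fold change of each list with at least 5 measured members was ranked among 10000 random lists of the same size matched on mean expression in 10 bins, with a two-sided share whose smallest possible value is 1e-04. These ranks describe the pools only.

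Genes to be named were also chosen by a rule fixed before the data were examined, among probe sets with 1 symbol. In each of the 4 comparisons that involve a transgenic or knockout line, it took the 10 largest rises and the 10 largest falls among called probe sets without overlap between the arrays of the groups (a separation that chance gives in 33.3% of cases). It also took up to 4 members of each list, called ones first, up to 20 genes of the combined pattern, and Scap, Srebf1 and Srebf2 where measured. Between the wild type pools it took the 5 largest changes each way.

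The procedure was tested on simulated data for the comparison of TgSREBP-1a with wild type, with 12411 probe sets, 200 of them changed, in 20 draws. The 8 measured genes of cholesterol synthesis were raised 2-fold besides. It recovered 48.8% of changes of 1.5-fold, 98.3% of 2-fold and 99.8% of 3-fold, with 0 in the wrong direction and 6.05 false calls per draw. In the same draws the comparison of Scap-/- with its wild type, in which nothing was changed, gave 0.35 calls per draw. The simulated noise was independent between arrays and equally wide in all groups. Real duplicates differed with an SD of 0.246 and 0.225 in the Scap study, and 0.162 and 0.172 in the wild type and TgSREBP-1a pools. The 0.35 can therefore be too low for the real Scap arrays. A raised list lay above the middle 95% of random lists in 20 of 20 draws, and an unchanged one lay outside the middle 95% in 1 of 20.

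The alternatives tried were: fold change alone on averaged duplicates, no size threshold, a 2-fold threshold, a replicate block for the hybridisation number, only the 4 arrays of the groups compared, another variance prior (trend and robust), cyclic loess, repeated quantile normalization, centring on the median, only the brighter probe sets (those above the median), the mean of all probe sets of a gene, and leaving out each array in turn. Leaving out the probe sets of the pancreatic genes Cpb1, Cela3b and Ctrc, with 1 probe set without a symbol, was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.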

Results

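The data are expression values for 12411 probe sets on 10 liver arrays, 2 for each of 5 RNA pools. Duplicate arrays correlated at 0.9944 for the wild type pool of the transgenic study, 0.9936 for TgSREBP-1a, 0.9891 for TgSREBP-2, 0.9871 for the wild type pool of the Scap study and 0.9888 for Scap-/-. The second TgSREBP-2 array correlated more closely with the second wild type array of its study (0.9915) than with its own duplicate. In the Scap study, every array correlated more closely with an array of the other group than with its own duplicate. The first Scap-/- array and the second wild type array there correlated at 0.993.

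The targeted gene, Scap, was measured first. The brighter of its probe sets read 7.94 and 7.75 on the log2 scale on the Scap-/- arrays and 9.24 and 8.89 on those of their wild type pool. It read 8.79 and 8.51 in the wild type pool of the transgenic study, 8.95 and 8.54 in TgSREBP-1a, and 9.16 and 8.87 in TgSREBP-2. In Scap-/- liver it fell by 1.22 ± 0.18 (limma, adjusted p = 0.018). This call ended when either Scap-/- array or the first wild type array was left out, with only 4 arrays in the fit, or with the mean of both probe sets. The other Scap probe set was dim, with a change of 0.12. Where either probe set lies relative to the deleted part of the gene is not given in the sources used here, so their values are a limited check of the labels. Srebf2 was dim on all arrays, and its changes lay between -0.21 and 0.22. No probe set was assigned to Srebf1, and the human transgenes had no known probe set.

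Which genes responded to SREBP-1a was asked by comparing TgSREBP-1a with its wild type pool. Fasn, the fatty acid synthase, rose by 2.83 ± 0.16 (7.12-fold; limma, adjusted p = 6.9e-06), and Acaca, the carboxylase before it, by 2.44 ± 0.14 (5.44-fold). Insig1, which retains SCAP in the endoplasmic reticulum, rose by 3.03 ± 0.24 (8.17-fold), and Pmvk of the mevalonate pathway by 2.98 ± 0.25 on its brighter probe set, while its other probe set read -0.09. Among probe sets with a symbol, the falls were led by the pancreatic enzymes Cpb1 (-4.67 ± 0.21) and Cela3b (-3.84 ± 0.16), followed by the liver's Saa4, C8a, Sult2a8 and Egfr. In all, 169 probe sets rose and 101 fell.

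Of 8 measured genes of cholesterol synthesis, 6 rose in TgSREBP-1a, 0 fell and 2 did not pass, and 7 rose when adjusted over the list alone. Their median log2 change was 1.61. Of 13 genes of sterol uptake, transport and the SREBP pathway, 4 rose (Insig1, Stard4, Aacs and Mylip), also when adjusted over the list alone. Of 15 genes of fatty acid synthesis, elongation and desaturation, 6 rose, also when adjusted over the list alone, among them Acss2 (2.49 ± 0.21), which makes acetyl-CoA from acetate, and the desaturase Fads2 (2.28 ± 0.14). The other 9 lay near 0, so that the list median was 0.09. Among 4 genes of NADPH production, malic enzyme Me1 rose by 2.35 ± 0.29. Of 21 genes of glycerolipid and phospholipid synthesis, 2 rose (3 adjusted over the list alone), namely Pnpla3 and Lpin1. Of 5 lipid droplet genes, 2 rose (3 adjusted over the list alone), Abhd5 and Hilpda, with a median of 0.70. Of 10 genes of fatty acid oxidation, the thioesterases Acot2 (1.66 ± 0.15) and Acot1 were among 3 that rose, while Crot (-1.52 ± 0.22) and the receptor gene Ppara (-1.15 ± 0.19) fell, and the counts were the same adjusted over the list alone. Of 10 genes of bile acid synthesis and sterol efflux, the transporters Slco1a4 (1.38 ± 0.15) and Abcg5 (1.34 ± 0.15) rose, and adjusted over the list alone 3 rose and 1 fell.

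Outside lipid synthesis, 3 of 4 measured acute phase genes fell in TgSREBP-1a, also adjusted over the list alone: Saa4 (-2.74 ± 0.16), Itih4 (-1.51 ± 0.26) and Steap4 (-0.78 ± 0.15). C8a (-2.60 ± 0.24) and C8b (-2.22 ± 0.16), chains of a complement component, fell. So did Egfr (-2.48 ± 0.22), Aox3 (-2.39 ± 0.25), Ugt2b1 (-2.37 ± 0.22) and Sult2a8 (-2.53 ± 0.25). C8a was the 1 of 5 hepatocyte markers that fell, and the median of that list was -0.31, below nearly all random lists (two-sided share 0.0088). Of 10 endothelial markers, Lyve1 rose by 0.64 ± 0.10, and the list median was 0.21, above nearly all random lists (two-sided share 0.0026). Among 3 macrophage markers, Cd163 rose by 0.91 ± 0.15. Gstt3 and Gstm4 rose among 8 xenobiotic and glutathione enzymes and Oasl1 among 14 interferon-stimulated genes. Sdf2l1 fell among 7 genes of the unfolded protein response, of which 1 rose and 2 fell adjusted over the list alone. The median of that list was -0.27, below nearly all random lists (two-sided share 8e-04). No gene was called on 18 measured genes of amino acid breakdown by limma over all probe sets, although the list median was -0.25, below all random lists (two-sided share 1e-04, the smallest possible), and 1 rose and 1 fell adjusted over the list alone.

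In limma, 339 probe sets had an adjusted p under 0.05 and 270 also changed by at least 1.5-fold. The count was 149 without the first wild type array, 164 without the second, and 142 without the first TgSREBP-1a array. Of 45 named calls, 33 held without each array in turn. Those lost in at least 1 case were Hsd17b7, Lpin1, Abhd5, Acot1, Cd163, Mylip, Lyve1, Gstm4, Sdf2l1, Steap4, Ppara and Itih4.

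The same question for SREBP-2 gave a response centred on cholesterol synthesis. All 8 measured genes of that list rose in TgSREBP-2, also adjusted over the list alone, with a median of 2.11. Hsd17b7, an enzyme late in the pathway, rose by 3.02 ± 0.32 (8.11-fold; limma, adjusted p = 0.0014), Pmvk by 2.85 ± 0.25 on its brighter probe set, Idi1, the isomerase of isopentenyl diphosphate, by 2.79 ± 0.16 (6.91-fold) and Cyp51, the lanosterol demethylase, by 2.72 ± 0.15 (6.61-fold). In all, 42 probe sets rose and 20 fell.

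Of 13 genes of sterol uptake and the SREBP pathway, 3 rose in TgSREBP-2, also adjusted over the list alone: Insig1 (2.36 ± 0.24), the sterol carrier Stard4 (2.14 ± 0.20) and Aacs (1.36 ± 0.17). Of 15 genes of fatty acid synthesis, 4 rose (5 adjusted over the list alone), namely Acss2 (1.95 ± 0.21), Acsl3 (1.24 ± 0.15 on its brighter probe set, -0.20 on the other), Fasn (1.20 ± 0.16) and Acaca (1.06 ± 0.14). The sterol transporter Abcg5 rose by 1.61 ± 0.15, the 1 call among 10 genes of bile acid synthesis and efflux (2 adjusted over the list alone). Cds1 was the 1 call among 21 glycerolipid genes. The transferrin receptor Tfrc, the 1 measured erythroid marker, rose 2.83-fold. The array's control probe set for Tfrc, left out of the tests, read 5.48 and 5.38 in TgSREBP-2 and 5.25 and 5.27 in wild type. Of 3 pancreatic acinar genes Ctrc rose by 1.51 ± 0.10, and all 3 rose adjusted over the list alone. Falls were smaller, and included the monooxygenase-like Moxd1 (-1.32 ± 0.11), Ddah1 (-1.17 ± 0.13), the thioesterase Acot1 (-1.15 ± 0.18) and Etnppl (-1.13 ± 0.13). Steap4 was the 1 of 4 acute phase genes that fell. Among interferon-stimulated genes, 0 of 14 were called by limma (1 rose adjusted over the list alone), with a median of 0.14. Amino acid breakdown had 0 calls of 18 (1 fell adjusted over the list alone) and a median of -0.35, below all random lists.

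In limma, 64 probe sets had an adjusted p under 0.05, and 62 were called. The count was 25 without the first wild type array, 28 without the second, 39 without the first TgSREBP-2 array and 124 without the second. Of 28 named calls, 15 held without each array in turn, and those of Aacs, Acsl3, Fasn, Acaca, Cds1, Tfrc, Ywhaq, Steap4, Slc25a30, Hsd17b6, Ppp1r3c, Acot1 and Gm4952 did not.

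Loss of SCAP, asked in the Scap-/- comparison, lowered genes of the same pathways. Insig1 fell by 2.53 ± 0.24 (5.78-fold lower; limma, adjusted p = 0.0013). Hsd17b7 (-2.39 ± 0.32), Acss2 (-2.33 ± 0.21), Idi1 (-2.26 ± 0.16) and Pmvk (-2.20 ± 0.25 on its brighter probe set, 0.21 on the other) fell too. Of 34 called probe sets, 32 fell and 2 rose. The rises were Fam25c (1.41 ± 0.14, with 0.18 on its other probe set) and Tnfrsf12a (0.87 ± 0.11), a receptor of the TNF family.

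Of 8 genes of cholesterol synthesis, 6 fell in Scap-/- (7 adjusted over the list alone), with a median of -1.37. Of 13 genes of sterol uptake and the SREBP pathway, 4 fell, also adjusted over the list alone: Insig1, Stard4, Scap itself and Aacs. Of 15 genes of fatty acid synthesis, 3 fell (7 adjusted over the list alone): Acss2, Acacb (-1.19 ± 0.15) and Fads2 (-1.13 ± 0.14). Gstt3 fell by 0.89 ± 0.12, the 1 call among 8 xenobiotic enzymes. The pancreatic genes Cpb1 (-3.21 ± 0.21) and Cela3b (-1.89 ± 0.16) fell here as well, 2 of 3 measured acinar genes, as in TgSREBP-1a. On the bile acid list 0 of 10 genes were called by limma (2 fell adjusted over the list alone), with a median of -0.44. Amino acid breakdown had 0 calls of 18 (2 fell adjusted over the list alone) and a median of -0.31, and interferon-stimulated genes 0 of 14 with a median of -0.21. Each of these medians lay below all random lists.

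At an unadjusted p under 0.05, limma gave 960 probe sets. Duplicates of the Scap study differed more widely than those of the wild type and TgSREBP-1a pools of the transgenic study. The spread shared by all groups can therefore make p-values of the Scap-/- comparison too small. With the hybridisation number as a replicate block 91 were called, though no label says that the number marks a batch. The count of 34 calls became 10 without the second Scap-/- array, 11 without the first wild type array, 68 without the second and 5 with only 4 arrays in the fit. Of 17 named calls, 7 held without each array in turn, and those of Tnfrsf12a, Gstt3, Nsdhl, Aacs, Fads2, Acacb, Scap, Stard4, Pmvk and Hsd17b7 did not.

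The series title names a combined analysis to find direct targets, so the lists were overlaid. Higher in both transgenic lines and lower in Scap-/- were 11 probe sets. They stand for Insig1, Pmvk, Acss2, Stard4 (2 probe sets), Hsd17b7, Idi1, Cyp51, Aacs, Nsdhl and a probe set without a symbol. Of these, Pmvk, Idi1, Cyp51, Nsdhl and Hsd17b7 belong to cholesterol synthesis, Acss2 and Aacs activate acetate and acetoacetate, Stard4 carries sterols and Insig1 controls SREBP activation. The opposite pattern held 0 probe sets by limma calls. Since only 2 probe sets were called higher in Scap-/-, this 0 says little. The list of 28 higher in both lines met the list lower in Scap-/- more often than the 0.072194 given by independent lists (Fisher's exact test, two-sided, p = 1e-22). Both lists rest on 1 shared spread per probe set and lean to bright probe sets. In the brighter part lay 32 of 34 calls in Scap-/- and 218 of 270 in TgSREBP-1a. That p-value can therefore be too small. Lower in both transgenic lines were 12 probe sets. In 20 draws simulated without any change, with the wild type arrays shared, at most 0 probe sets were higher in both lines and at most 1 lower in both. These draws held hybridisation noise only. They cannot say how many such probe sets a peculiarity of the shared wild type pool would give. Taking TgSREBP-1a by itself, 19 probe sets were higher there and lower in Scap-/-, among them Fads2, Acacb, Rarres1, Gstt3, Camk1d and Tlcd1. With TgSREBP-2 there were 12, the further one being Sc5d. Rarres1, Camk1d, Tlcd1 and Sc5d were picked out after their values were seen.

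**Figure D1:**
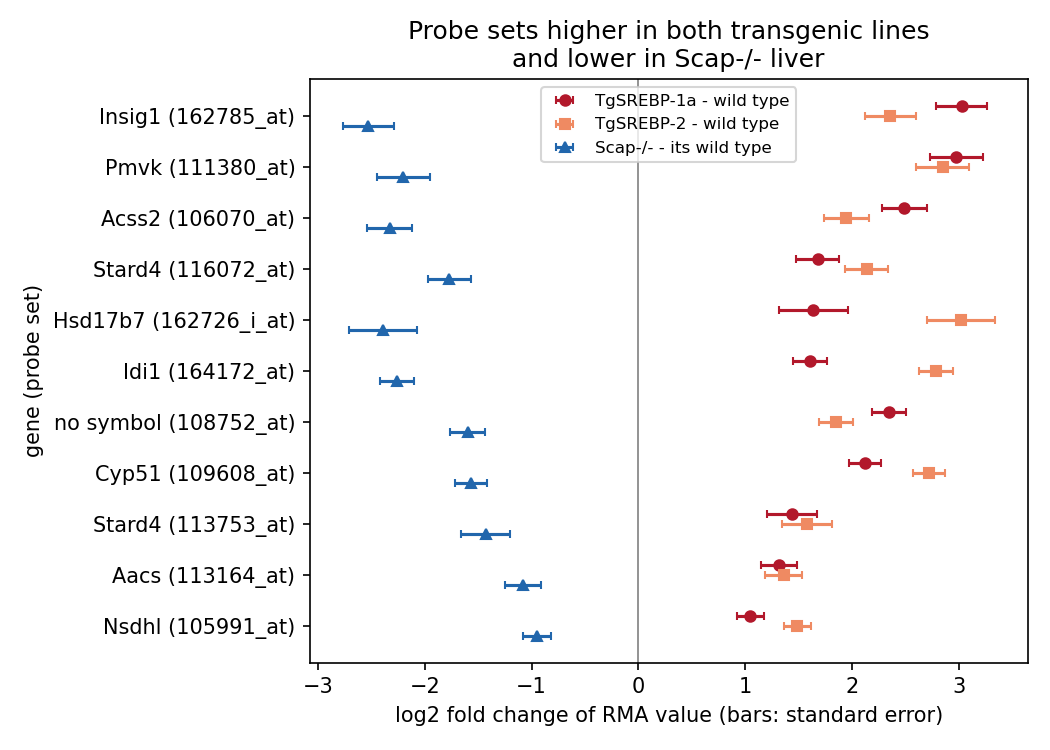
Log2 fold change of the RMA value (x axis, bars: standard error) for the 11 probe sets of the combined pattern (y axis) in TgSREBP-1a, TgSREBP-2 and Scap-/-, each against its wild type pool with 2 arrays per pool. The transgenic values run from 1.05 to 3.03 and the Scap-/- values from -2.53 to -0.95.

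The pattern held 5 probe sets without the second Scap-/- array, 7 without the first wild type array of that study and 2 with only 4 arrays in each fit. With the hybridisation number as a replicate block it held 18, and by fold change alone 25, each with all 11 among them. Across all probe sets the log2 fold changes of TgSREBP-1a and Scap-/- had a Pearson r of -0.036 and a Spearman rho of -0.023, and those of TgSREBP-2 and Scap-/- -0.021 and 0.13. The values for TgSREBP-2 and Scap-/- ranged from -0.163 to 0.12 (Pearson) and -0.003 to 0.232 (Spearman) with 1 array left out. The first hybridisations alone gave a Pearson r of 0.144 there and the second -0.172. Genes are not independent replicates. TgSREBP-1a and TgSREBP-2 had 0.367 and 0.247, below the 0.5 that shared wild type arrays give without any change, while their covariance of 0.019 exceeded the simulated 0.00875. The simulated values hold hybridisation noise only, without any difference between pools. With 1 array left out their Pearson r ranged from 0.241 to 0.444 and their Spearman rho from 0.13 to 0.382.

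The transgenic lines were also compared directly. TgSREBP-1a stood higher for 5 of 15 fatty acid genes and TgSREBP-2 for Idi1 of cholesterol synthesis. Fasn was higher in TgSREBP-1a by 1.64 ± 0.16 (3.11-fold; limma, adjusted p = 0.00044), Fads2 by 1.58 ± 0.14, Acacb by 1.48 ± 0.15 and Acaca by 1.38 ± 0.14, and the count of 5 was the same adjusted over the list alone, with a list median of 0.30. Of 8 genes of cholesterol synthesis, 1 was lower in TgSREBP-1a, Idi1 (-1.18 ± 0.16), and 3 adjusted over the list alone, with a median of -0.45. In all, 147 probe sets were higher in TgSREBP-1a and 84 lower.

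**Figure D2:**
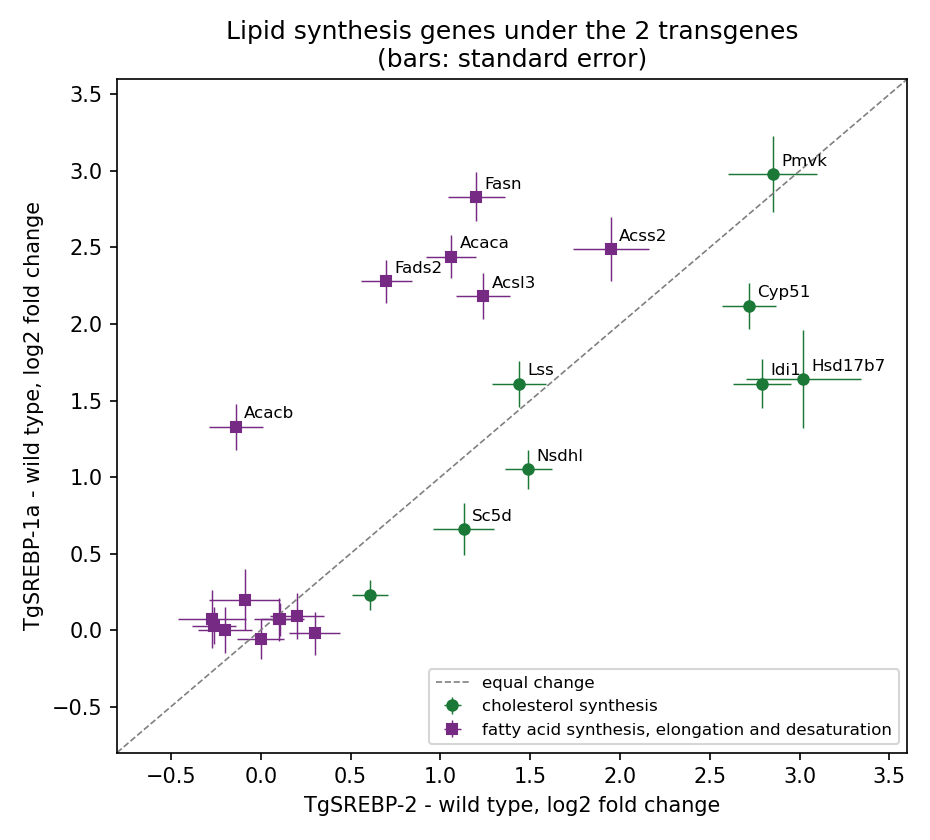
Log2 fold change against the shared wild type pool in TgSREBP-2 (x axis) and TgSREBP-1a (y axis) for measured genes of cholesterol synthesis (circles, 8 genes) and of fatty acid synthesis (squares, 15 genes), with standard errors as bars. Fasn lies at 1.20 and 2.83, and Idi1 at 2.79 and 1.61, on opposite sides of the dashed line of equal change.

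Other genes higher in TgSREBP-1a than in TgSREBP-2 were Rarres1 (2.68 ± 0.21), Pctp (2.66 ± 0.28), a phosphatidylcholine carrier, the retinol dehydrogenase family member Rdh9 (2.36 ± 0.23), Gstt3 (2.03 ± 0.12), B4galt6 (1.95 ± 0.12) and Heg1 (1.68 ± 0.18). Of 5 lipid droplet genes 3 were higher, also adjusted over the list alone: Hsd17b13 (1.93 ± 0.24), Abhd5 (1.24 ± 0.17) and Hilpda (0.69 ± 0.09). Of 10 genes of fatty acid oxidation 3 were higher (Acot1, Acot2 and Acot3) and 1 lower (Crot), and 2 were lower adjusted over the list alone. Me1, Lpin1, Pnpla3, Gpt2, Cd163, Lyve1, Ptprb, Mylip, Slco1a4 and Oasl1 were higher too. Lower in TgSREBP-1a were Cpb1 (-5.30 ± 0.21), Cela3b (-4.47 ± 0.16), Ctrc (-1.72 ± 0.10), C8a (-2.58 ± 0.24), Saa4 (-2.42 ± 0.16), Fetub (-1.85 ± 0.13), Egfr (-1.86 ± 0.22), Itih4, Tfrc, Cds1 and Cyp39a1. The 7 genes of the unfolded protein response had 0 calls by limma (1 higher adjusted over the list alone) and a median of -0.29.

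**Figure D3:**
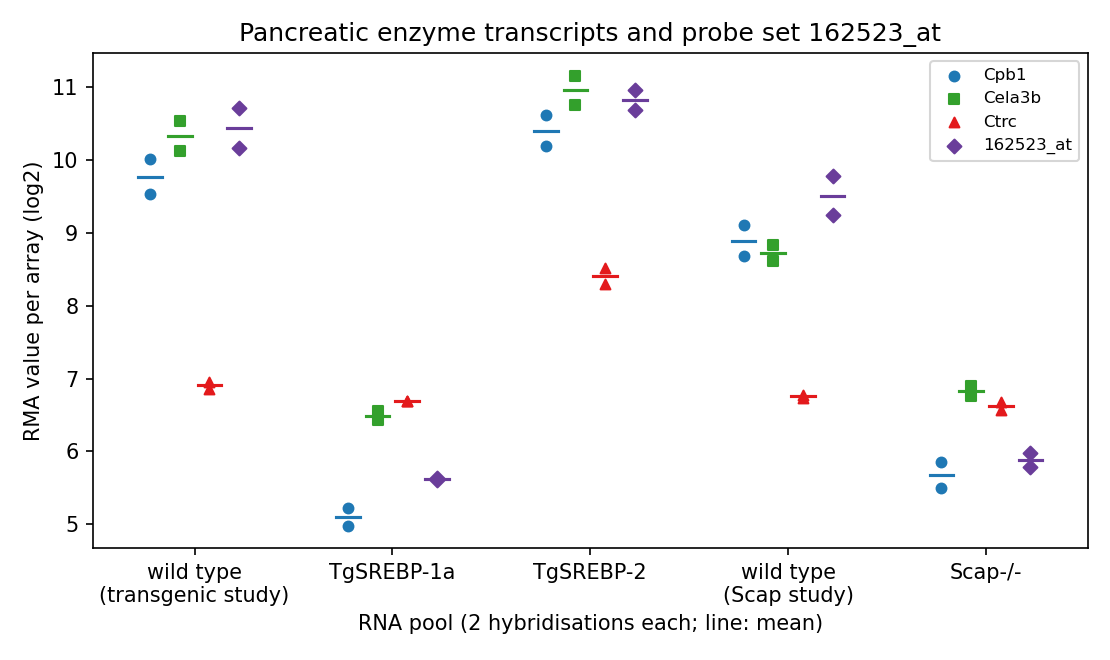
RMA value per array on the log2 scale (y axis) of the pancreatic genes Cpb1, Cela3b and Ctrc and of a probe set without a symbol (diamonds) in the 5 RNA pools (x axis), with 2 arrays per pool as points and their mean as a line. Cpb1 reads 5.22 and 4.98 in TgSREBP-1a and 10.62 and 10.19 in TgSREBP-2.

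In limma, 282 probe sets differed between the lines at an adjusted p under 0.05, and 231 were called. The count was 87 without the first TgSREBP-1a array, 142 without the second, 122 without the first TgSREBP-2 array and 384 without the second. Of 42 named calls, 28 held without each array in turn, and Idi1, Me1, Lpin1, Abhd5, Gpt2, Ptprb, Mylip, Slco1a4, Oasl1, Acot3, Cyp39a1, Itih4, Tfrc and Crot were lost in at least 1 case.

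The wild type pools, which differ in diet, age, injections and breeding, gave the size of such differences without a transgene or knockout. Gstp3, a glutathione transferase, was higher in the pool of the transgenic study by 3.11 ± 0.17 (8.65-fold; limma, adjusted p = 3.7e-05), followed by Fgl1 (1.67 ± 0.22), Acot1 (1.64 ± 0.18), Cela3b (1.61 ± 0.16) and Etnppl (1.44 ± 0.13). Rarres1 (-2.55 ± 0.21), Serpina4-ps1 (-2.07 ± 0.15), Aox3 (-2.04 ± 0.25), Idi1 (-1.83 ± 0.16) and Pmvk (-1.66 ± 0.25) were lower there. Of 8 genes of cholesterol synthesis, 5 were lower in the pool of the transgenic study (7 adjusted over the list alone), with a median of -1.35. All 11 probe sets of the combined pattern read lower in that pool, 8 of them called, with a median of -1.23. Of 14 interferon-stimulated genes 1 was lower (5 adjusted over the list alone), with a median of -0.47. Of 18 genes of amino acid breakdown 0 were called (1 was higher adjusted over the list alone), with a median of -0.21 (two-sided share 8e-04). The median of that list was thus negative under SREBP gain, under SCAP loss and between wild type pools. In all, 19 probe sets were higher and 44 lower. The count of 63 became 17 and 14 without the first and the second array of the transgenic study's pool, 22 and 120 without those of the Scap study's pool, and 13 with only 4 arrays. Fgl1, Acot1, Pmvk and Aox3 lost their call in at least 1 of these cases.

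The remaining lists held few or no calls against wild type. Cell cycle (7 measured genes), the mitochondrial respiratory chain (8), collagen and stellate cells (5), lymphocytes (4), cholangiocytes (4), the cytoskeleton (5), lipoproteins (4) and glycolysis (4) had 0 calls by limma in the TgSREBP-1a, TgSREBP-2 and Scap-/- comparisons. All 12411 probe sets together gave 270, 62 and 34 calls there, so lists this short can hold 0 by that share alone. At an unadjusted p under 0.05, without a size threshold, all probe sets gave 1279, 983 and 960. Mttp of the lipoprotein list read -0.01 in TgSREBP-2 on its brighter probe set and fell by 1.70 on its other one. Of the neutrophil markers 0 were measured.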

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

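Chosen after the results were seen were the tests of the pancreatic genes, of the hepatocyte share and of the second TgSREBP-2 array, for which slope and medians had both been seen before they were assigned to explanations; the tests of the complement and male-biased lists were set before their values were seen.

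A difference between the transgenic lines, tested directly in limma, marked 231 probe sets. Of single genes it marked Acot1, a thioesterase of fatty acid metabolism, which rose by 1.05 ± 0.18 in TgSREBP-1a and fell by 1.15 ± 0.18 in TgSREBP-2, a difference of 2.20 ± 0.18 (adjusted p = 0.00013). Each of these changes from wild type lost its call when single arrays were left out.

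Cpb1 and Cela3b, enzymes of the exocrine pancreas, were far lower in TgSREBP-1a and in Scap-/- than in their wild type pools. A graded response to SREBP activity is argued against, since Cpb1 changed by -3.21 in Scap-/- and by -4.67 in TgSREBP-1a, the same way under loss and gain. Pancreatic tissue of 1 composition in all pools is argued against: Cela3b exceeded Cpb1 by 0.73 ± 0.27 in the difference between the wild type pools, and Ctrc rose by 0.87 ± 0.23 more than Cpb1 from wild type to TgSREBP-2, which shared their diet and age range. Within the transgenic study it stays open for Cpb1 and Cela3b. Their changes to TgSREBP-2 differed by 0.00 ± 0.27, while those to TgSREBP-1a stood 0.83 ± 0.27 apart (1.32 ± 0.27 in Scap-/-), with Cpb1 the lower. That gap goes against it unless background holds up the low readings of Cela3b, and no value here settles that. The errors of these differences between genes treat the genes as independent, although they were read on the same arrays. In wild type, Cpb1 read 10.01 and 9.53 and Cela3b 10.54 and 10.12. In TgSREBP-2 they read 10.62 and 10.19, and 11.16 and 10.76. There the genes shifted together between duplicates, so the error of 0.27 can be too wide. A genotype effect also stays open, since each genotype is 1 pool.

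C8a, C8b, Saa4, Egfr and other liver transcripts were lower in TgSREBP-1a. A lower hepatocyte share stays open. The 26 markers of other cell types stood above 5 hepatocyte markers, C8a among them, by 0.39 (bootstrap SD 0.55). That is too wide to set against the median of -1.01 of 73 genes, which were picked for falling. Complement and coagulation genes without C8a and C8b (6 measured) had a median of -0.27, lower than most random lists but short of 1.5-fold, which leaves a fall of that group undecided. Male-biased liver genes (5 measured) had a median of -0.73, below all random lists (share 1e-04, the smallest possible), with Susd4 and C6 called lower, so a fall of male-biased transcripts may be part of the pattern. This is a hypothesis on 5 genes, C6 is on both lists, and Cspg5 and Obp2a read -0.02.

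Every array of the Scap study lay closer to an array of the other group there than to its own duplicate, which was not tested further. In the transgenic study, the second TgSREBP-2 array lay closer to the second wild type array (correlation 0.9915) than to its own duplicate (0.9891). Over 29 probe sets lower in Scap-/-, its changes followed those of the first array with a slope of 0.95 (bootstrap SD 0.04). That argues against RNA without the SREBP response, such as wild type RNA alone. The pancreatic probe sets, and the probe set without a symbol that fell most in Scap-/-, were left out of this slope. Since TgSREBP-1a raised many of the same probe sets, the slope cannot tell TgSREBP-1a RNA from TgSREBP-2 RNA. Cpb1 read 10.19 on this array, and 5.22 and 4.98 in TgSREBP-1a. Wild type RNA as 0.5 or more of the second array's RNA is argued against too. The fold changes of both arrays give a share of 0.00 (bootstrap SD 0.12), which reaches 0.25 at 2 bootstrap SD above. A share within that bound or RNA of another pool stays open, since the median changes had a ratio of 0.57 (bootstrap SD 0.67), too wide to decide. An effect of the hybridisation number shared with the other groups is argued against as the reason for this closeness. After removal of their mean difference, the correlation with the duplicate minus that with the closest other array was -0.0087. That removal cannot speak to an effect of the number particular to TgSREBP-2. The second TgSREBP-2 array also had the lowest maximum, 12.22, where the other arrays reached 12.86 to 13.39. Its control for the 3′ end of Gapdh read 11.50, and 12.45 on its duplicate. In the wild type pool of that study the control read 11.83 and 12.14. Whether a fault of the array itself plays a part was not tested. No biological explanation was tested, as both arrays hold 1 pool.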

How the results depend on the processing

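Leaving out the pancreatic enzyme probe sets, together with 1 probe set without a symbol, was chosen after the data were seen. The other alternatives were set before. With 1 array left in a group, that array is assumed to vary like the other groups. The pattern lower in both transgenic lines and higher in Scap-/- held 0 probe sets in each alternative run on it. Few probe sets were higher in Scap-/- at all, 2 in the main fit and 31 by fold change alone, so these counts say little. Calls were 133 (TgSREBP-1a), 38 (TgSREBP-2), 115 (between the transgenic lines) and 33 (between the wild type pools) at 2-fold, where the stricter threshold is the cause. By fold change alone, without a test, they were 158 for TgSREBP-2, 169 for Scap-/-, 366 between the transgenic lines, 202 between the wild type pools and 25 for the combined pattern. With the hybridisation number as a replicate block they were 101 for TgSREBP-2, 91 for Scap-/-, 145 between the wild type pools and 18 for the combined pattern, and no call was lost. Differences between duplicates correlated at 0.34 to 0.60 among the 4 groups other than TgSREBP-2, but at -0.17 to 0.11 with TgSREBP-2. By these correlations the numbers do not pair the arrays throughout, and each comparison holds only 2 such pairs. The 18S control nevertheless read higher on the second array in every pool, TgSREBP-2 included (2.09). A shift shared by the second arrays is therefore not excluded as a source of the difference between these counts. With only 4 arrays in the fit, which leaves fewer degrees of freedom, 5 were called for Scap-/-, 13 between the wild type pools and 2 in the combined pattern. That setting gave 352 for TgSREBP-1a, 65 for TgSREBP-2 and 298 between the transgenic lines. Fewer degrees of freedom by themselves thus do not account for the drops. Differences between duplicates had an SD of 0.246 in the wild type pool of the Scap study and 0.225 in Scap-/-. In the transgenic study it was 0.162 in wild type, 0.172 in TgSREBP-1a and 0.221 in TgSREBP-2. The fit of all 10 arrays shares 1 spread per probe set, so its p-values for the Scap study can be too small. Whether this accounts for the drops was not tested. Leaving out 1 array gave 142 to 193 for TgSREBP-1a, 25 to 124 for TgSREBP-2, 10 to 68 for Scap-/-, 87 to 384 between the transgenic lines, 14 to 120 between the wild type pools and 5 to 15 for the combined pattern; the cause was not tested. The correlation of TgSREBP-1a with Scap-/- ranged from -0.143 to 0.081 (Pearson) and -0.16 to 0.114 (Spearman) with 1 array left out. It was -0.103 without the pancreatic probe sets and the one without a symbol. The latter had the largest fall of all probe sets in both comparisons (-4.82 and -3.63). For Chrna4, TgSREBP-1a against wild type turned from 0.00 on its brightest probe set to 1.24 as the mean of its probe sets, since another reads 2.49. Of 284 gene values, 281 kept their direction and side of the threshold under cyclic loess, 275 under repeated quantile normalization and 282 under median centring. Of 270 calls in TgSREBP-1a, 218 lay in the brighter part of the probe sets. Most called genes with several probe sets were not called on all of them. All probe sets agreed for 16 of 65 such genes in TgSREBP-1a, 3 of 16 in TgSREBP-2 and 2 of 12 in Scap-/-. They agreed for 9 of 66 between the transgenic lines and 0 of 16 between the wild type pools. Opposite calls within a gene numbered 0 in each comparison.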

Other observations

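Genes lower in both TgSREBP-1a and Scap-/- were singled out after their values were seen. They were Ttc39c (-0.81 and -1.14), Serpina4-ps1 (-0.71 and -1.22), Deptor (-0.62 and -0.95), an inhibitor of mTOR signalling, the pancreatic genes Cpb1 and Cela3b, and a pair of probe sets without a symbol (-2.78 and -1.75, and -4.82 and -3.63). Serpina4-ps1 (-0.87) and the first of that pair (-1.47) were called lower in TgSREBP-2 as well. In the other direction, Tnfrsf12a rose in TgSREBP-1a (1.36) and in Scap-/- (0.87), and Fam25c fell by 1.58 in TgSREBP-1a while it rose by 1.41 in Scap-/-. Lower in Scap-/- and called in neither transgenic line were Scap, Atxn1 (-0.70), Epm2aip1 (-0.61) and the carboxylesterases Ces1e (-1.11) and Ces1f (-1.56 on 1 of its probe sets).

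Control probe sets for the 3′ end of 18S ribosomal RNA read higher on the second array than on the first in all 5 pools, by 1.94 in the wild type pool of the transgenic study, 2.53 in TgSREBP-1a, 2.09 in TgSREBP-2, 0.79 in the wild type pool of the Scap study and 1.48 in Scap-/-.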
